A study of Mus musculus with 6 samples.

How the data were processed

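Total RNA from the livers of 6 mice was hybridised to Illumina bead arrays, 1 array per mouse. An Illumina bead array reads each transcript with beads that all carry one probe, so a value is the mean over many beads. Per the labels' protocols, RNA was extracted with Trizol, cleaned on a column with DNase treatment and amplified as biotin-labelled cRNA. Of the 6 mice, 3 had received PTU alone and 3 had received PTU and T3. The labels name each array as a mouse of its own. They do not give the sex, strain or age of the mice, the dose or duration of either drug, or how mice were allotted to the groups. The scanner table places the arrays on 2 slides. Slide 1 held PTU mice 1 and 3 and PTU+T3 mice 1 and 3, and slide 2 held PTU mouse 2 and PTU+T3 mouse 2. Replicate numbers follow the order of the records and pair no mice.

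The deposited scanner table holds, for 25697 probes and each array, a mean bead signal, its standard error, the number of beads and a detection p-value. Per the file headers, the intensity values were exported from BeadStudio by its gene expression module (BSGX 3.2.7) with normalization set to none. The authors' detection p-value compares a probe with the negative control probes of the same array, per the file headers. A second deposited table holds the authors' processed log2 values for the same probes. Over the 2125 probes with a mean scanner signal above 1000, those values rose with the log2 of the scanner signal with slopes of 1.00 to 1.02, so they are on a log2 scale and not centred. Each array has the same median of 7.83 there. How the authors' values were background-corrected and normalized is not given in the sources used here, and they served only as an alternative.

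The main analysis began from the deposited intensity values. Background was corrected with limma's normexp model, fitted to the signals of 798 negative control probes, with an offset of 16, and the arrays were quantile-normalized together on the log2 scale. The control probes form a block of 832 rows whose columns carry chip positions in place of mouse names. They were joined to the arrays by column position. For 14 housekeeping probes listed in both blocks, all 14 signals were identical in the same column on each array and 0 were identical in any other column. An alternative that does not need this join takes the background from the detection p-values.

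Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, which left 12196 probes. A gene was represented by its passing probe with the highest mean over all 6 arrays, a choice that does not use the groups, which gave 9234 of the 18117 genes on the array. Of the 511 genes that passed the test, 148 had another passing probe, and for 9 of them another probe differed in sign. Symbols in the table were updated through the Entrez ID with a gene table of assembly GRCm38.p6. It matched 23681 of the probes, changed the symbol of 4172, and left 2016 with the symbol of the file. The build of the probe coordinates is not given in the sources used here, and 8.44% of 21801 coordinates fell inside the gene of that assembly, so no coordinates are printed. Chromosomes of named genes are those of the scanner table, and distances between genes were measured on that assembly. Probe sequences were not aligned again here, so probes for the close relatives in the Mup, Serpina1, Gsta, Acot, Cyp2b and Cyp4a families can each pick up transcripts of another member.

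PTU+T3 was compared with PTU with limma's lmFit and eBayes on log2 intensity (two-sided), with Benjamini-Hochberg adjustment over all genes tested and an adjusted p under 0.05. Errors of log2 differences are standard errors of that fit, and errors of levels are SDs over 3 mice. A gene not detected on any array of a group has only a bound there. Its fold is then written as "at least", from the mean of the brighter group over the dimmer group's mean of, per array, the higher of the lowest detected signal and the probe's own. Such a bound holds only on the background-corrected scale of the main analysis. The number of arrays, 3 per group, limits the precision.

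A set of 27 gene lists was fixed before the data were examined: pathways of thyroid hormone action and liver metabolism, and markers of liver and other cell types. The 25 lists with at least 5 tested genes were tested with limma's camera with a preset correlation of 0.01, which compares a list's genes with all other genes, with adjustment over the lists. Camera with an estimated correlation, rank-based camera and fry were run beside it. fry's directional p asks whether a list's genes moved, on balance, one way, and its mixed p whether they changed in either direction, neither against other genes. Each list also has a count adjusted over the list alone.

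Genes named here follow a rule fixed before the data were examined. They are the 12 genes with the largest positive and the 12 with the largest negative difference among those that passed with no overlap between the groups, skipping gene models without a proper symbol (1 in each direction). Then come up to 4 members per list with the smallest adjusted p, or the 2 brightest members where none passed. Thrb, Thra, Dio1, Thrsp, Me1, Hr, Klf9, Cyp7a1 and Alb are always given. The rule named 80 genes, of which 58 passed the test. Of the 16 of these with another passing probe, 0 had one of opposite sign. A gene named outside the rule is marked as such. A result that the rule would give is not reported here.

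Alternatives changed one choice at a time: the background correction, the normalization between arrays, the authors' values, the filter, the probe summary, the variance model, the threshold, the slide or the number that opens each mouse's label as a block, and each mouse left out in turn. Chosen after seeing the data were the background from detection p-values, slide 1 alone, the fit without pancreas and muscle genes, and the fit without PTU+T3 mice 2 and 3. Slide 2 holds 1 mouse of each group, so it gives values with no test.

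The gene and list tests were checked on simulated data built from the means and residual SDs of the 9234 genes, with 200 genes changed in each of 20 simulations of 3 against 3. The fit found 6.5% of changes of 0.5 log2 units, 57.5% of changes of 1, 91.4% of changes of 2 and 98.4% of changes of 4, and 4.30% of its calls were false. A list of 20 genes shifted by 1 log2 unit was found in 100% of simulations, at an unadjusted camera p under 0.05. The real lists were called at an adjusted p and most shifted by less, so this figure does not carry over to them. All simulated genes vary independently, so this does not test how correlation within a list affects the calls. Nor does it test variation that genes of a mouse share, so the shares found and false need not hold for the real calls. R 4.3.3, limma 3.58.1 and the data.table package (1.17.8) were used, with Python 3.11.15 and matplotlib 3.10.9 for the plots.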

Results

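The series asks how thyroid hormone changes gene expression in the mouse liver. PTU, in this field the abbreviation of propylthiouracil, blocks the synthesis of thyroid hormone, and T3 (triiodothyronine) is the active form of the hormone. Livers of 3 mice given PTU alone were compared with livers of 3 mice given PTU and T3. Between 11801 and 12320 of 25697 probes were detected per array, with a median of 38 to 40 beads per probe. No 2 arrays held identical values. Across genes, log2 intensities correlated with a mean Pearson r of 0.979 within groups (6 pairs) and 0.954 between groups (9 pairs); genes are not independent replicates. The first principal component held 61.0% of the variance and placed the PTU mice at -21.9, -30.4 and -30.5 and PTU+T3 mice 2 and 3 at 40.5 and 36.4. PTU+T3 mouse 1 stood between them at 5.91.

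T3 raised 256 genes and lowered 255 of the 9234 tested. Dio1, the type 1 deiodinase that both activates and clears thyroid hormone, had the largest increase among the probes that represent genes. It was not detected in any PTU liver, where it measured 4.77 ± 0.15 log2 units (SD, n = 3), and stood at 12.86 ± 0.74 with T3 (n = 3). On the scale of the main analysis it was at least 242-fold higher (adjusted p = 0.000319). Its smallest log2 difference over the alternatives was 4.90, against 8.09 in the main result, and it was called in all 27 that tested it. Its other probe differed by 6.95 log2 units. The major urinary protein genes Mup4 and Mup2, of a family of pheromone carriers, lie on chromosome 4 like Dio1. Mup4 had 1 passing probe, which can pick up transcripts of other members of the family. Mup4 rose by 6.80 ± 0.37 log2 units (SE; adjusted p = 0.00103) and Mup2 by 5.87 ± 0.46 (adjusted p = 0.0061), with a difference of 9.09 for its other probe. Among the genes that fell, the acyl-CoA thioesterase gene Acot3 changed the most, by -5.02 ± 0.90 log2 units (adjusted p = 0.0342).

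The other genes with the largest increases were Tlcd2 (29.3-fold), Sult5a1, a sulfotransferase gene (25.8-fold), Slc25a45, of the mitochondrial carrier family (23.4-fold), and Cyp17a1, the steroid 17-alpha-hydroxylase gene (21.0-fold). Sqle, which encodes squalene epoxidase of sterol synthesis, rose 17.7-fold and Serpina1e, one of the mouse alpha-1-antitrypsin genes, 17.1-fold. Acot11, Nudt7, a peroxisomal coenzyme A hydrolase gene, and Chrna4 rose 12.5-fold, 12.4-fold and 11.5-fold. On the other side, Etnppl (Agxt2l1 in the scanner table), which encodes the lyase of phosphoethanolamine, fell to a level 12.9-fold below PTU. The glutathione S-transferase gene Gsta1 was 11.3-fold lower and Gsta2 9.63-fold lower. Acot1 was 11.2-fold lower, and the transcription factor gene Olig1 9.88-fold lower. Krt23, Osbpl3, Cbr3, Slc17a8, Cyp4a31 and Vldlr, the very low density lipoprotein receptor gene, were 5.54-fold to 9.32-fold lower. Besides Dio1 and Mup4, the adjusted p of these genes lay between 0.0061 and 0.0499. With the slide as a block it was 0.00177 for Dio1 and Mup4. Of the others that rose, Cyp17a1 (0.066), Sqle (0.0542), Nudt7 (0.0504) and Chrna4 (0.0646) lost the call with that block. So did all that fell except Vldlr (0.039), with values up to 0.0811. Folds also depended on the processing. The smallest log2 differences over the alternatives were 2.41 for Tlcd2, 1.93 for Sult5a1 and 1.23 for Chrna4. In the main result these were 4.87, 4.69 and 3.53. For Serpina1e and Nudt7 they were 3.73 and 3.21, against 4.10 and 3.64. Among the lowered genes, Olig1 reached -1.05, against -3.30.

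**Figure D1:**
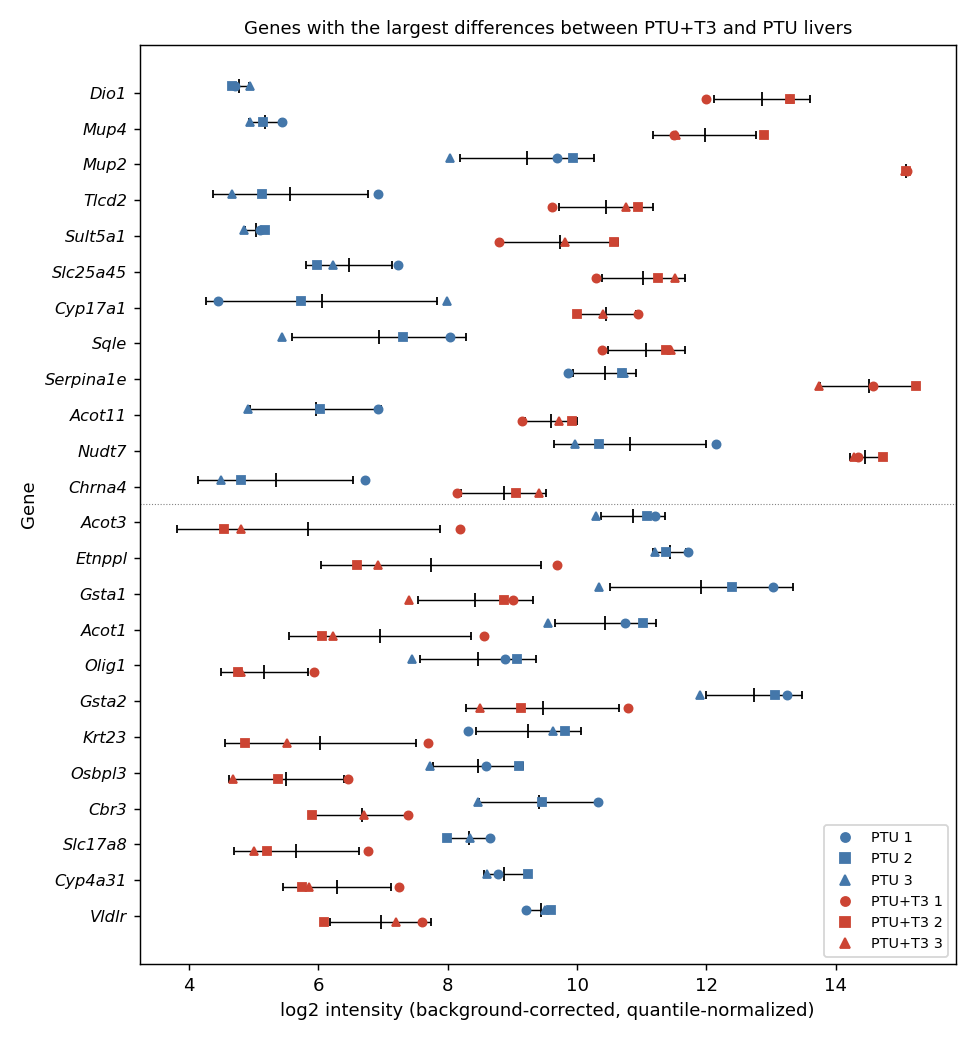
Log2 intensity of the 12 genes with the largest increases and the 12 with the largest decreases (above and below the dotted line), with a symbol per mouse, PTU in blue and PTU+T3 in red, and the mean and SD of each group in black (n = 3). The groups do not overlap for any of the 24 genes, with means from 4.77 against 12.86 for Dio1 to 10.86 against 5.85 for Acot3, and for each of the 12 lowered genes PTU+T3 mouse 1 is the mouse with T3 nearest to the PTU group.

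Of the 511 genes, 301 differed at least 2-fold, 184 of them higher and 117 lower with T3. At least 4-fold differences were found for 60 higher and 22 lower genes. All 511 had groups that did not overlap, which fixes their sign on each slide. Without regard to the test, the groups did not overlap for 3075 genes, or 33.3%, where chance gives 10%. With the slide as a block limma called 75 genes higher and 18 lower, and on slide 1 alone, with 2 mice per group, 2 higher and 0 lower, with 1076 genes in all at an unadjusted p under 0.05. The counts moved with every mouse left out. They were 60 higher and 4 lower without PTU mouse 1, 4 and 0 without PTU mouse 2, and 99 and 51 without PTU mouse 3. They were 476 and 628 without PTU+T3 mouse 1, 21 and 1 without PTU+T3 mouse 2, and 21 and 0 without PTU+T3 mouse 3. Of the 58 named genes that passed, 18, 3 and 28 kept the call without PTU mice 1, 2 and 3, and 57, 9 and 8 without PTU+T3 mice 1, 2 and 3, and 18 kept it with the slide as a block. In the 2 fits with 1 mouse left out and 0 lower genes, 1837 and 1989 genes had an unadjusted p under 0.05. The 4 genes that passed in every fit with 1 mouse left out were Dio1, Mup2, Mup4 and Bcl6. Bcl6, a transcriptional repressor gene, is named outside the rule, after its values were seen, and rose by 3.08 ± 0.19 log2 units (SE). Without normalization between arrays, 27.0% of the calls were increases, against 50.1% in the main result.

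Genes of thyroid hormone action were led by Dio1. In the list of known T3 target genes, 3 of 17 tested genes rose and 0 fell (7 higher and 1 lower adjusted over the list alone). Besides Dio1 these were Bcl3, which rose by 3.15 ± 0.40 log2 units (SE), and Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase gene, which rose by 2.76 ± 0.41. The PTU mean of Bcl3, 4.89, lay near background. Its smallest log2 difference over the alternatives was 0.86, and that of Gpd2 was 1.56. The median over the list was 0.74 (camera adjusted p = 0.000718; adjusted p = 0.466 with an estimated correlation). The median is the same with Dio1 at its bound. The call was lost with probes detected at p under 0.01 on all 6 arrays (median 0.32, camera adjusted p = 0.14). That filter asks for detection in every mouse and so leaves out Dio1, Bcl3, Hr and Me1, which makes it a test of a different list. The range of the adjusted p over the alternatives was 2.54e-05 to 0.14. The median was 0.40 without PTU+T3 mouse 3 and 0.26 without PTU+T3 mice 2 and 3, with the list called in both. Thrsp, a lipogenic gene and long-known T3 target, differed by 4.10 ± 1.25 log2 units (adjusted p = 0.0913). Its 3 PTU mice spread from 6.98 to 12.78. Hr, a corepressor gene, differed by 1.39 ± 0.33 (adjusted p = 0.0556), Klf9 by 0.32 ± 0.21 (adjusted p = 0.386), and Me1 (Mod1 in the scanner table), the malic enzyme gene, by 1.11 ± 1.51 (adjusted p = 0.676). Me1 stood at 4.96 in PTU+T3 mouse 3 and at 11.50 in PTU+T3 mouse 2. Among the receptors, Thra measured 6.30 ± 0.38 in PTU and 6.16 ± 0.13 with T3 (SD, n = 3; adjusted p = 0.698). The 1 probe for Thrb, the main receptor gene of the liver, was not detected on any array, and Thrb was not tested. Of the 18 tested genes of receptors, cofactors and hormone transport, 1 rose, again Dio1, and 0 fell, the same counts as adjusted over the list alone. That list had a median of -0.18, a mean of 0.11 and a camera test pointing down (adjusted p = 0.994).

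Of 21 tested genes of cholesterol synthesis and uptake, 4 rose and 0 fell, and 17 rose adjusted over the list alone. They were Sqle, Sc5d, which rose by 2.66 ± 0.36 log2 units (SE), Cyp51 by 2.24 ± 0.38 and Dhcr7 by 1.77 ± 0.34, all enzymes of the sterol pathway. Of the 21 genes, 20 had a positive difference, and the median was 1.38 (camera adjusted p = 2e-09; adjusted p = 0.466 with an estimated correlation of 0.619). The medians of PTU mice 1, 2 and 3 stood at 0.56, 0.04 and -0.67 log2 units from the PTU mean. Without PTU mouse 3 the median difference was 0.96. Fatty acid and triglyceride synthesis had a median of 0.74 (camera adjusted p = 0.00646; adjusted p = 0.671 with an estimated correlation). In that list 1 of 20 genes rose, Mlxipl, the ChREBP transcription factor gene, by 1.59 ± 0.29, and 1 fell, the phosphatidate phosphatase gene Lpin2, by -1.21 ± 0.22 (2 higher and 1 lower adjusted over the list alone). This list lost its call without PTU mouse 3 (median 0.31, adjusted p = 0.13; range over the alternatives 6.26e-06 to 0.13), and its median was 1.17 without PTU mouse 1. The medians of PTU mice 1, 2 and 3 stood at 0.53, -0.04 and -0.56.

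Of 18 tested genes of bile acid synthesis and transport, 4 rose and 0 fell (5 higher and 2 lower adjusted over the list alone). Cyp7b1 and Cyp27a1, enzymes of the alternative route from cholesterol to bile acids, rose by 2.55 ± 0.24 and 1.70 ± 0.20 log2 units (SE). Abcb11, the bile salt export pump gene, rose by 1.14 ± 0.23 and Abcg8, of the sterol exporter, by 0.90 ± 0.14. Cyp7a1, which encodes the rate-limiting enzyme of the classical route, differed by 0.53 ± 0.66 (adjusted p = 0.646). The list's median was 0.33 (camera adjusted p = 0.0117; adjusted p = 0.466 with an estimated correlation), and its call was lost without PTU mouse 3 (median 0.14, adjusted p = 0.12; range over the alternatives 0.00179 to 0.12). Without PTU+T3 mice 2 and 3 the median was 0.20, and the list was called.

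Of 27 tested genes of xenobiotic metabolism, 7 fell and 1 rose (13 lower and 2 higher adjusted over the list alone). Besides Gsta1 and Gsta2, Ephx1, the microsomal epoxide hydrolase gene, fell by -1.65 ± 0.26 log2 units (SE), Gsta4 by -1.21 ± 0.23 and Nr1i2, which encodes the pregnane X receptor, by -0.90 ± 0.15. The gene that rose was the sulfotransferase gene Sult1d1, by 0.80 ± 0.15, named after its values were seen. The median was -0.96 (camera adjusted p = 4.82e-05; adjusted p = 0.466 with an estimated correlation), at -0.63 on slide 1 and -1.32 on slide 2, and at -0.47 without PTU+T3 mice 2 and 3, where the list was called. Of 26 genes of fatty acid oxidation and ketogenesis, 1 fell, Acot1, and 0 rose (7 lower and 0 higher adjusted over the list alone). Acot1 encodes a thioesterase that splits acyl-CoA and is no enzyme of beta oxidation itself. The median was -0.27 (camera adjusted p = 0.0168; adjusted p = 0.466 with an estimated correlation), with the call lost without PTU mouse 1 (median -0.17, adjusted p = 0.0984) and without PTU+T3 mice 2 and 3 (adjusted p = 0.111; range over the alternatives 0.00236 to 0.111).

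Of 31 tested subunit genes of oxidative phosphorylation, 3 rose and 0 fell (6 higher and 0 lower adjusted over the list alone): Cox5a by 0.83 ± 0.14 log2 units (SE), Ndufb3 by 0.62 ± 0.14 and Cyc1 by 0.56 ± 0.12. The median was 0.23 (camera adjusted p = 4.82e-05; adjusted p = 0.466 with an estimated correlation). The median was 0.15 with scaling to the 75th percentile and 0.07 without normalization between arrays (adjusted p = 0.0139; range over the alternatives 9.9e-08 to 0.0139). Skeletal muscle transcripts were high in PTU+T3 mouse 3, whose median for this list was 0.19 above the PTU mean, against 0.19 and 0.28 in mice 1 and 2. In the list of endoplasmic reticulum and integrated stress response, 3 of 16 genes rose and 0 fell (9 higher and 1 lower adjusted over the list alone). The chaperone genes Hyou1 and Pdia4 rose 2.82-fold and 1.95-fold, and Asns, the asparagine synthetase gene, 2.31-fold. The folds of Hyou1 and Asns depended on the processing. Their smallest log2 differences over the alternatives were 0.293 and 0.19, against 1.497 and 1.208 in the main result. For Pdia4 the smallest was 0.79, against 0.966. The median was 0.57 (camera adjusted p = 0.00602; adjusted p = 0.466 with an estimated correlation). The median was 0.22 with every probe by itself, 0.20 with the authors' values and 0.34 with no background correction, with the list called in each. Pancreatic transcripts were high in PTU+T3 mouse 2, whose median here was 0.67, against 0.38 and 0.53 in mice 1 and 3, and the list was called with mouse 1 as the only mouse with T3. Ribosomal protein genes had a median of -0.20, with 16 of 16 differences negative and 0 genes past the gene test in either direction, also adjusted over the list alone (camera adjusted p = 0.0296; adjusted p = 0.613 with an estimated correlation). That call was lost without PTU mouse 3 (adjusted p = 0.12), PTU+T3 mouse 1 (0.0594) or PTU+T3 mouse 3 (0.137), and without PTU+T3 mice 2 and 3 together (0.114; range over the alternatives 0.000633 to 0.137). Without normalization between arrays the median was -0.37. Its brightest members, Rpl23 and Rplp1, differed by -0.20 ± 0.14 and -0.17 ± 0.13.

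**Figure D2:**
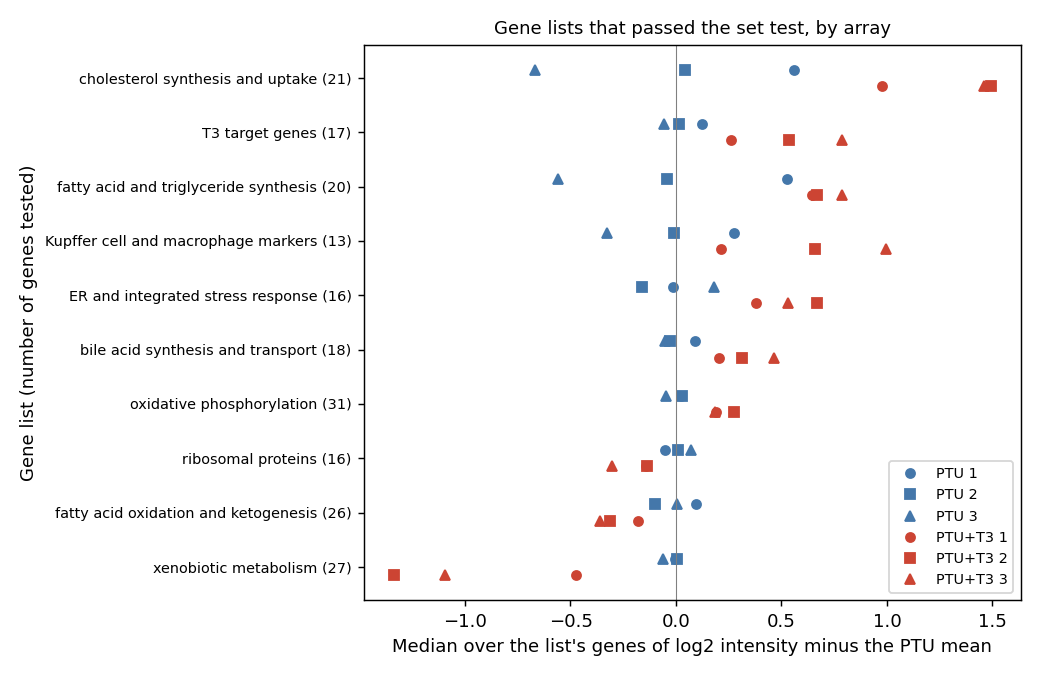
For each of the 10 gene lists that passed the set test, the median over its genes of log2 intensity minus the mean of the 3 PTU mice, with a symbol per mouse, PTU in blue and PTU+T3 in red. Medians of the mice with T3 lie above those of PTU for the cholesterol list (0.98 to 1.49 against -0.67 to 0.56) and below them for xenobiotic metabolism (-1.34 to -0.47 against -0.06 to 0.00), and for the Kupffer cell list PTU+T3 mouse 1 (0.21) lies below PTU mouse 1 (0.28).

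Of 19 tested genes of growth hormone signalling and male-biased expression, 4 rose and 0 fell (6 higher and 1 lower adjusted over the list alone). Elovl3, a fatty acid elongase gene, rose by 3.05 ± 0.30 log2 units (SE) and Hsd3b5, a steroid dehydrogenase gene, by 3.02 ± 0.45, beside Nudt7 and Cyp7b1. The PTU mean of Elovl3, 4.70, lay near background. Its smallest log2 difference over the alternatives was 0.73, and that of Hsd3b5 was 2.67. The list did not pass (median 0.16, camera adjusted p = 0.0844), but passed without PTU mouse 1 (median 0.12, adjusted p = 0.0266), with no filter on dim probes (0.0416) and with every probe by itself (0.0408; range over the alternatives 0.0266 to 0.213). Of 7 female-biased genes 1 fell, Acot3, and 2 rose, Cyp17a1 and Cyp2b13 (2 higher and 2 lower adjusted over the list alone). Cyp2b13 was not detected in any PTU liver and was at least 1.37-fold higher with T3 on the scale of the main analysis. Its log2 difference was 0.75 there and at the smallest 0.10 over the alternatives, of which 12 of 27 kept the call. This list had a median of -0.13, a mean of -0.88 and a camera test pointing up (adjusted p = 0.994).

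In the list of Kupffer cell markers, the resident macrophages of the liver, 13 of 13 differences were positive with a median of 0.60 (camera adjusted p = 0.000209; adjusted p = 0.466 with an estimated correlation). Of these genes 1 rose, the lysozyme gene Lyz2, by 1.55 ± 0.34 log2 units (SE), the same count as adjusted over the list alone, and 0 fell. The medians of PTU+T3 mice 1, 2 and 3 were 0.21, 0.66 and 0.99 above the PTU mean, and that of PTU mouse 1 was 0.28 above it. PTU+T3 mouse 2 carried pancreatic and PTU+T3 mouse 3 muscle transcripts, fry's directional adjusted p was 0.133, and without mice 2 and 3 the list was not called (adjusted p = 0.111; range over the alternatives 3.92e-06 to 0.111). Hepatocyte markers had 1 lower gene of 12 and 0 higher, the same adjusted over the list alone (median 0.10, camera adjusted p = 0.434). The gene was Alb, by -1.37 ± 0.29, but its probe was detected on 4 of 6 arrays and measured 4.65 to 6.70, near background, so it does not measure the abundant albumin transcript. Of 4 lymphocyte and neutrophil genes, Cd3e fell by -1.68 ± 0.29 (also adjusted over the list alone). Its probe measured 4.57 to 6.90, near background like that of Alb. The lymphocyte and neutrophil list was too short for a set test (median 0.06, mean -0.29). The erythroid list had 0 of 5 genes past the test (median 1.02, camera adjusted p = 0.366), with Hba-a1 at 1.35 ± 0.63 and Alas2 at -1.38 ± 0.46. It had a median of 0.07 without PTU mouse 3 and passed with the number of the labels as a block (median 1.60, adjusted p = 0.0147; range over the alternatives 0.0147 to 0.781). Stellate cell, endothelial and bile duct markers had 0 of 10, 0 of 13 and 0 of 5 genes past the test, with medians of 0.17, -0.17 and 0.05 (camera adjusted p = 0.58, 0.58 and 0.994). Their brightest members differed by -0.12 ± 0.13 (Dcn), -0.48 ± 0.14 (Reln), -0.26 ± 0.13 (Clec4g), -0.29 ± 0.13 (Egfl7), -0.42 ± 0.22 (Spp1) and 0.11 ± 0.33 (Cldn7). Another probe of Dcn and of Egfl7 differed in sign. None of these 4 lists gained a gene adjusted over the list alone.

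The remaining lists did not pass the set test in the main result. Of 20 genes of glucose and glycogen metabolism, 3 rose and 1 fell (6 and 3 adjusted over the list alone). Gpd2, Eno1, an enolase gene of glycolysis, by 1.38 ± 0.31 log2 units (SE), and Ppp1r3b, a glycogen targeting subunit gene, by 0.96 ± 0.17, rose, and Ugp2, which supplies UDP-glucose, fell by -1.26 ± 0.25 (median -0.27, mean 0.09, camera adjusted p = 0.994). Of 24 genes of the urea cycle and amino acid breakdown, 1 rose, the proline dehydrogenase gene Prodh, by 1.45 ± 0.20 (1 higher and 1 lower adjusted over the list alone; median -0.11, camera adjusted p = 0.994). Of 20 lipoprotein genes, 1 rose, Apof, by 1.01 ± 0.22 (2 and 2 adjusted over the list alone; median 0.00, camera adjusted p = 0.641). Of 13 clock genes, Clock rose by 0.95 ± 0.19 (3 higher and 6 lower adjusted over the list alone; median -0.55, camera adjusted p = 0.366). Of 13 antioxidant genes, the glutathione peroxidase gene Gpx1 rose by 0.74 ± 0.15 (1 higher and 3 lower adjusted over the list alone; median -0.28, camera adjusted p = 0.11). None of 19 acute phase genes passed, also over the list alone (median 0.11, mean -0.01, camera adjusted p = 0.366), with Hpx at 0.47 ± 0.14 and Hamp at 0.03 ± 0.13. None of 12 cell cycle genes passed, and 2 rose adjusted over the list alone (median 0.13, camera adjusted p = 0.11), with Ccnd1 at 1.11 ± 0.50 and Mcm4 at 0.14 ± 0.17. Some of these lists passed under an alternative. The cell cycle list passed with no filter on dim probes (adjusted p = 0.0144), with detection in at least 1 array (0.0363) and with every probe by itself (0.0475), in a range over the alternatives of 0.0144 to 0.381. The antioxidant list passed with no filter (0.0438), with every probe by itself (0.0248) and by fry's directional p, in a range of 0.0248 to 0.211. The clock list passed with every probe by itself (0.0262; range 0.0262 to 0.724) and the acute phase list on slide 1 alone (0.0438; range 0.0438 to 0.88).

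In all, camera with the preset correlation called 7 lists higher and 3 lower. With an estimated correlation it called 0 lists, and at an unadjusted p under 0.05 it had 1 higher and 0 lower. fry's directional p called 3 higher, the T3 target, oxidative phosphorylation and stress response lists, and 1 lower, the antioxidant list (adjusted p = 0.0496), which camera did not call. The 3 lists that camera called lower and the cholesterol list were at 0.0776. fry's mixed p called 19 lists in either direction. With the slide as a block the same numbers of lists, 7 and 3, were called. With the authors' values the median was 0.29 for the T3 targets, 0.38 for fatty acid synthesis, 0.73 for cholesterol, 0.21 for bile acids and 0.22 for Kupffer cells. With no background correction it was 0.32 for the T3 targets, 0.42 for fatty acid synthesis, 0.22 for bile acids and 0.33 for Kupffer cells. Without normalization between arrays it was 0.20 for bile acids. All of these lists were called in those fits.

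Transcripts of the exocrine pancreas were high in 1 PTU+T3 liver. The list of pancreas and adipose markers had 3 tested genes, too few for a set test, and 0 passed the gene test or the test over the list alone (median 1.47). Amy2, an amylase gene, stood at 12.37 in PTU+T3 mouse 2 and between 7.51 and 8.74 in the other mice. Ctrb1, a chymotrypsinogen gene, stood at 8.93 in PTU+T3 mouse 2 and between 4.62 and 5.14 elsewhere. Genes of skeletal muscle were high in PTU+T3 mouse 3, such as Acta1, the skeletal actin gene (12.65 against 4.27 to 4.41), and Ckm, the muscle creatine kinase gene (9.92 against 4.34 to 4.86). These muscle genes come from a list written after the arrays were seen. Of the 17 pancreas and muscle genes that were tested, 0 were called. A gene high in a single mouse with T3 has a large spread, such as an SD of 2.12 for Amy2, which works against a call. The count therefore does not show that this RNA left the other calls unaffected.

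**Figure D3:**
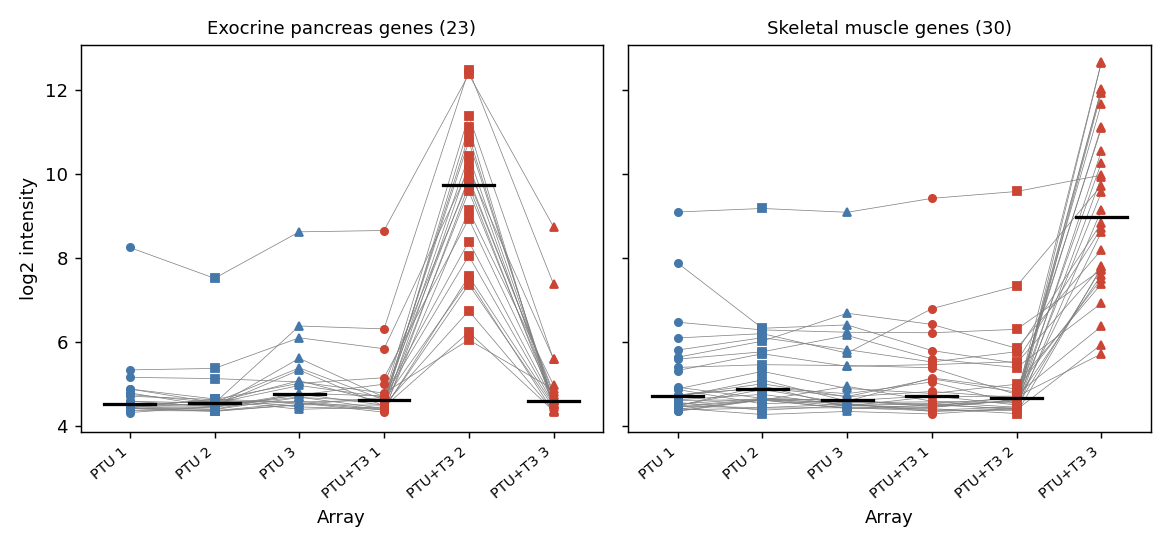
Log2 intensity of 23 exocrine pancreas genes (left) and 30 skeletal muscle genes (right) on each array, from lists written after the arrays were seen; a symbol is a gene, thin lines join a gene's values, and black bars are medians. The pancreas median is 9.72 in PTU+T3 mouse 2 and 4.51 to 4.75 in the other mice, and the muscle median is 8.98 in PTU+T3 mouse 3 and 4.60 to 4.88 in the others.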

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

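Of the 58 named genes that passed, none changed sign under any alternative, and of 1605 values 994 stayed past the threshold and 611 did not. For the 10 called lists, 247 of 260 values from camera with the preset correlation stayed past it and 0 changed sign, but camera with an estimated correlation called 0 of the 10 and fry's directional p 3. For the 58 genes the groups do not overlap, so leaving out mice or taking a single slide could not turn a sign. Where a value below has no stated cause, the cause was not tested.

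With each mouse left out in turn, the genes higher with T3 ranged from 4 to 476, the genes lower from 0 to 628, and the genes changed at least 2-fold from 4 to 621. An arm of 2 mice leaves fewer residual degrees of freedom, but the count rose without PTU+T3 mouse 1. In the same fits, camera with the preset correlation called 5 to 8 lists higher and 2 or 3 lower; all calls of the full set of mice are lost with an estimated correlation.

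Genes lower with T3 numbered 434 with an offset of 50, 389 with no background correction, 570 with no normalization between arrays, 401 with eBayes with trend and robust, and 394 with detection p under 0.01 on all 6 arrays. They numbered 162 with detection in at least 1 array. No background correction gave 158 genes changed at least 2-fold, since the uncorrected background shrinks the folds. The authors' values gave 164 higher and 64 changed at least 2-fold. With no filter on dim probes, 88 were higher, 53 lower and 89 changed at least 2-fold, over 18117 genes tested. With every probe by itself, 390 probes were higher and 5 lists lower. Array quality weights gave 515 higher, 689 lower and 501 changed at least 2-fold, with the lowest weights for PTU mouse 3 (0.712) and PTU+T3 mouse 1 (0.718).

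A 1.2-fold threshold inside the test gave 84 higher, 18 lower and 99 changed at least 2-fold. At an adjusted p under 0.01, 17 genes were higher, 0 lower and 17 changed at least 2-fold, and 1 list was lower, from 2497 genes at an unadjusted p under 0.05. At an adjusted p under 0.1 there were 608, 809 and 456.

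With the slide as a block, 75 genes were higher, 18 lower and 89 changed at least 2-fold. All 93 were among the 511. The number that opens each mouse's label, taken as a replicate block, gave 8 higher, 0 lower and 8 changed at least 2-fold. It gave 8 lists higher, with 1895 genes at an unadjusted p under 0.05. PTU mouse 2 is the only mouse with its number, so with this block it adds nothing to the comparison. Without PTU mouse 2 and with no block, 4 genes were higher and 0 lower. The fall in calls therefore cannot be laid to the number. The 3 pairs of mice from opposite groups that share this number were compared by their deviations from the group means. These correlated across genes with r of 0.21, 0.20 and -0.0015. Over all genes the deviations thus did not follow the number in all 3 pairs, but some genes on chromosome 2 did, as given below. The 2 positive values were the highest of all 9 such pairs, which leaves a partial effect of the number open. PTU+T3 mouse 2 correlated best with a mouse of another number (0.069).

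Chosen after the data were seen, slide 1 alone gave 2 higher, 0 lower and 2 changed at least 2-fold. Leaving out PTU+T3 mice 2 and 3 gave 3, 0 and 3 genes and 1 lower list, with the lone mouse assumed to vary like the PTU mice and 840 genes at an unadjusted p under 0.05. Leaving out the pancreas and muscle genes gave 267 and 272, among them all 511. Of the 17 such genes tested, 0 had been called, so leaving them out could hardly remove a call. This fit does not test whether RNA of other tissues affected the calls.

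Camera with an estimated correlation gave 0 higher and 0 lower lists, and fry's directional p 3 and 1. The mean correlation between arrays of opposite groups was 0.736 over the 1000 most variable genes, against 0.954, by the choice of genes that differ.

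Signal over background limits the dim genes. Of the 58 named genes that passed, 39 were detected on all 6 arrays at a detection p under 0.01, and all 39 were called there.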

Other observations

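The tests of single arrays in this part were chosen after the result was seen. The counts over other splits of the mice were planned before.

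The annotation of biological processes in the scanner table gave a view that does not rest on the lists fixed beforehand. Of 227 process terms with at least 10 tested genes, camera with the preset correlation called 1 higher, cholesterol biosynthesis, with a median difference of 1.70 log2 units over 10 genes (adjusted p = 0.0283), and 0 lower. With an estimated correlation 0 terms were called, and 2 were higher and 0 lower at an unadjusted p under 0.05. Glycolysis came next, with a median of 0.38 over 22 genes (adjusted p = 0.0801).

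Some genes were low in PTU mouse 3 alone. Scd1, the main hepatic desaturase gene, measured 11.74 there and 14.63 to 15.04 in the other 5 mice. Cyp7a1 measured 9.75 there against 11.69 to 12.66, and Hba-a1, an alpha globin gene, 11.38 against 13.35 to 14.76. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty each had a probe detected on all 6 arrays, and of 2 Xist probes 1 was detected on 1 array and the other on 0.

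Other splits of the 6 mice into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 511 genes that differed, and 1 of the 10 splits reached that number, the real one, with 5 as the highest of the others. It gave 301 genes changed at least 2-fold, again reached by 1 split, with 5 as the highest of the others. It gave 10 lists past the threshold, which 2 of the 10 splits reached, with 10 as the highest of the others. That other split set PTU mouse 1 with PTU+T3 mice 2 and 3, which does not follow the slide. Like every other split it exchanges a mouse of each group, so it is not free of the T3 difference. PTU+T3 mice 2 and 3 still stood against PTU mice 2 and 3. Its count therefore does not show that a grouping without T3 would reach as many lists. The same split kept 2 of the 3 pairs that share the number of the labels on one side each, the 2 with the higher correlations (0.21 and 0.20), and parted the third. With that number as a block, 8 lists were higher and 3 lower.

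PTU+T3 mouse 1 lay between the groups for the genes that changed at least 4-fold in the fit without it. With 0 at the PTU mean and 1 at the mean of PTU+T3 mice 2 and 3, the median position on the log2 scale was 0.597 (bootstrap 95% interval 0.564 to 0.669) for 86 induced genes and 0.35 (0.313 to 0.414) for 71 repressed genes. A PTU mouse under the wrong label would stand near 0 for induced genes, and its Dio1 was at 0.849, which argues against that. RNA of a PTU liver might be mixed into a sample that otherwise responded like PTU+T3 mice 2 and 3. If that PTU liver stood at the PTU mean, induced and repressed genes would then have the same position on the linear scale. The repressed genes stood further along by 0.255 (0.179 to 0.327, over resampled genes of this mouse), which argues against a mixture with a liver at the PTU mean. Single PTU mice spread around that mean, from 10.33 to 13.03 for Gsta1 and from 5.44 to 8.04 for Sqle. A mixture with a single PTU liver need not give the same position, so it stays open. The same holds for a mixture in a liver that responded less. Without normalization between arrays the position over both kinds of genes was 0.469, so that step does not account for it. A smaller or earlier response of that mouse may account for it and was not tested, since the labels give no dose or time per mouse.

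PTU+T3 mouse 2 carried pancreatic transcripts and PTU+T3 mouse 3 skeletal muscle transcripts, which may have come from tissue taken along with the liver. In mouse 2 all 23 measured genes of the pancreas list were above the mean of the other mice, by a median of 4.60 log2 units, with Cela2a and Amy2 at 12.48 and 12.37; 9 of the 23 were detected in some PTU liver. In mouse 3 all 30 muscle genes were above it, by a median of 3.33, with Atp2a1 and Acta1 at 12.66 and 12.65. Of the 30, 13 were detected in some PTU liver. Both lists were written after the arrays were seen and keep only genes detected on at least 1 array. The choice itself thus favours an excess of these genes in these mice. Induction by T3 would raise them in each mouse given T3, but the higher median difference from PTU in the other 2 was -0.0076 for the pancreas list and -0.037 for the muscle list, which argues against it. Lists that did not depend on the arrays pointed the same way: 7 of 7 pancreas markers fixed beforehand were at least 1 log2 unit above all other arrays in mouse 2, as were 13 of 54 genes annotated to sarcomere, myofibril or muscle contraction in mouse 3, against at most 1 on any other array.

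In the PTU group, 24 genes stood at least 1.5 log2 units away from all other arrays in 1 mouse, by more than the range of the other 5, such as Pdrg1, at 4.46 in PTU mouse 2 and 7.33 to 8.82 elsewhere, and Ttc27, at 4.59 in PTU mouse 1 and 7.29 to 8.71 elsewhere. Inherited differences in linked regions would put such genes within 20 Mb of each other more often than random draws, and PTU mice 1 and 3 had 0 such pairs, where random draws gave 1.38 (permutation p = 1), but 24.1% of draws gave 0 too, and separate loci need not give pairs, so it stays open there. PTU mouse 2 had 2 pairs among 6 genes, Rmdn3 with Lrrc57 on chromosome 2 and Tomm22 with Slc25a17 on chromosome 15. Random draws gave 0.272 pairs (permutation p = 0.0233, or 0.0699 adjusted over the 3 mice), so an inherited difference may account for them and stays open. Pdrg1 also followed the number that opens the labels, which PTU mouse 2 shares with no other mouse. It stood at 8.82 and 8.51 in PTU mouse 1 and PTU+T3 mouse 3, which share a number. In PTU mouse 3 and PTU+T3 mice 1 and 2, which share another, it stood at 7.33 to 7.46. Rmdn3 and Lrrc57 had the same order of levels, and Tomm22 and Slc25a17 did not. Over all 3 mice the permutation p was 0.49, and with the coordinates of the scanner table, which do not place Slc25a17, it was 0.722 over all 3 and 0.166 for PTU mouse 2; the placement on the assembly was added after these were seen. Poorly filled probes would have few beads, but the median number on the array concerned was 38, which argues against that, and no biological explanation named by the design was tested.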
